A study of Mus musculus with 4 samples.

How the data were processed

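Gene expression was measured by RNA sequencing in inguinal white adipose tissue, a subcutaneous fat depot, of mice. The 4 libraries fall into 2 wildtype (WT) libraries and 2 libraries labelled as an adipose knockout of Flcn, the gene of the tumour suppressor folliculin. Groups and replicate numbers were taken from the library titles. Per the labels' protocols, RNA was extracted with Trizol and cleaned on columns before library preparation.

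The authors deposited 1 table per library with a log2 expression value for each of 13677 Ensembl genes. STAR, limma and the mouse build mm9 are named, without versions, per the submitters' processing notes. The annotation, the counting program and the strand setting are not given in the sources used here. The deposited log2 values had been brought to nearly the same distribution in the 4 libraries. Library medians lay between 10.7636 and 10.7645, and every library had a highest value of 21.66. The low end differed, with a lowest value of 1 in both WT libraries and knockout-labelled replicate 1 and of 2.37 in replicate 2. The values are not CPM, because 2 raised to each value summed to about 81869664 in WT replicate 1. Whole read counts could not be recovered from them, so the sequencing depth is unknown and no counting interval is given. Quantile normalization forces equal distributions, so a shift shared by most genes cannot be seen, and the most abundant transcripts sit at shared ceiling values. Gene symbols were matched by Ensembl identifier for 13592 genes, and 85 had no match. The reference annotation used for names is of another build than mm9, so no coordinates are given.

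The groups were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values, as a linear model with group as its only term. Variances were moderated with a trend on mean expression (residual degrees of freedom 2, prior degrees of freedom 3.09), tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 13677 genes with a threshold of 0.05. The filter set before the data were examined (a value of at least 0 in at least 2 libraries) had assumed log2 CPM and removed 0 genes. A log2 fold change is the mean of the libraries labelled knockout minus the WT mean.

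A total of 37 lists of pathway genes and cell type markers with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Beside it, camera was run with an estimated correlation and on ranks. With 2 residual degrees of freedom, a call lost with the estimated correlation does not show that the members of a list vary together. In addition fry was run, which asks whether the members of a list move one way on balance without comparing them with other genes. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named Flcn, the 10 largest rises and the 10 largest falls past the threshold with groups that did not overlap and a mean of at least 1, up to 4 members of each described list with the smallest p, and 21 genes named in advance. Genes outside the rule are said to be so where they appear, and some genes that the rule names are not reported here.

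The same fit was tested on simulated data with 13677 genes and 2 libraries against 2, of which 200 genes were changed in each of 20 runs. It recovered 24.8% of genes changed by 1 on the log2 scale, 69.8% of those changed by 2, 83.5% of those changed by 3 and 88.2% of those changed by 4. On average 6.9 of 140.05 called genes per run were false. The simulated variances came from the distribution that this fit had estimated, with noise independent between genes. These shares hold only where the real libraries follow that model, and do not measure false calls among the real ones. Of lists of 30 genes shifted by 0.5, camera called 20 of 20, and it called 0 of 800 unshifted lists. The simulated lists held no correlation between genes, so this says nothing of lists whose members vary together.

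Alternatives set in advance were other filters, repeated quantile normalization, median centring, variance moderation without the trend or with robust estimation, a block for the replicate number, and leaving out each library. Alternatives added after the data were seen were a filter on a mean of at least 8, centring on genes with a mean of at least 12, leaving out the muscle list and array weights. Sharing of sequence between genes was measured as the share of a gene's stretches of 31 bases found in transcripts of other genes. Figures were drawn with matplotlib 3.10.9.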

Results

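The transcriptome of inguinal white adipose tissue was compared between 2 WT libraries and 2 libraries labelled as Flcn adipose knockout. The series asks how folliculin, which acts with the mTOR pathway, relates to browning, the gain of heat-producing traits by white fat. The log2 values of 13677 genes were available per library, and the depth behind them is unknown. The median absolute log2 difference between libraries was 0.147 within WT and 0.247 within the knockout label, and lay between 0.268 and 0.307 across the groups. The design text speaks of animals, but no label ties a library to one animal, so p-values measure only the spread between these libraries.

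The targeted gene did not separate the groups. Flcn (ENSMUSG00000032633) had values of 12.36 and 12.21 in WT and 12.35 and 12.12 in the libraries labelled knockout, means of 12.28 ± 0.10 and 12.23 ± 0.16 (SD, n = 2). Its log2 fold change was -0.05 ± 0.13 (SE; limma adjusted p = 0.852), with a 95% interval from -0.39 to 0.29. It was 0.02 without WT replicate 1, -0.12 without WT replicate 2, -0.17 without knockout-labelled replicate 1 and 0.06 without replicate 2. The deleted part of the gene is not given, and the tissue also holds cells other than adipocytes, so this gene-level value does not check the labels. The groups are therefore called by their labels throughout.

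In the libraries labelled knockout, 134 genes were higher and 84 lower than in WT (limma, adjusted p under 0.05), and at an unadjusted p under 0.05 the counts were 1659 and 1402. All 218 called genes had groups that did not overlap. Over all genes 54.6% did, against 33.3% by chance for 2 against 2. Among the called genes, 98 rose and 68 fell by at least 2-fold. The largest rises in protein-coding genes with little shared sequence included Slc2a5, the fructose transporter, by 4.10 ± 0.39 on the log2 scale (SE, n = 2 per group; adjusted p = 0.0336), and Fbp2, the muscle form of fructose-bisphosphatase, by 3.31 ± 0.33. Lmntd1 rose by 4.87, the mitochondrial carrier gene Slc25a34 by 3.84, Cpn2 by 3.64, the melanosome transport gene Mreg by 3.64, Ociad2 by 3.49, the nicotinic receptor subunit gene Chrna2 by 3.35 and the ferroxidase-like gene Hephl1 by 3.34. Gm9696 had the highest log2 fold change, 6.81 ± 0.72, and shared 15.9% of its 31-base stretches with other genes.

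Among the falls, Gchfr, the feedback regulator of GTP cyclohydrolase, fell by 4.12 ± 0.48 on the log2 scale (SE, n = 2 per group; limma adjusted p = 0.0415). The values of Gchfr in the libraries labelled knockout, 5.02 and 6.13, were also low and coarse. Pon1, a serum esterase, fell by 2.97 ± 0.20. Log2 fold changes of the other falls were -2.55 for the matrix protease gene Adamts15, -2.53 for Anxa8, -2.52 for the epithelial transcription factor gene Trp63, -2.47 for the G protein subunit gene Gnal, -2.42 for Lrtm1 and -2.38 for the cadherin gene Celsr2. Eif3j2 (-4.86) and the major urinary protein gene Mup10 (-4.67) fell further, and both are uncertain because 94.9% and 83.2% of their 31-base stretches occur in transcripts of other genes. Without the mean-variance trend limma called 0 genes (2702 at an unadjusted p under 0.05). It also called 0 genes when any 1 library was left out, with unadjusted counts of 1395 without WT replicate 1, 1807 without WT replicate 2, 3281 without knockout-labelled replicate 1 and 3455 without knockout-labelled replicate 2.

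Of 30 measured members of the thermogenic list, 7 rose and 0 fell over all genes, and 22 were higher and 3 lower when adjusted over the list alone. The median log2 fold change was 1.66 (camera adjusted p = 1.23e-10; adjusted p = 0.456 with an estimated correlation). Cox8b, a respiratory chain subunit abundant in brown fat, rose from 12.32 ± 0.21 to 15.56 ± 0.51 (SD, n = 2), a 9.42-fold change (limma adjusted p = 0.0336). The coactivator genes Ppargc1a and Ppargc1b, which drive mitochondrial biogenesis, rose 2.18-fold (adjusted p = 0.0476) and 3.42-fold (adjusted p = 0.0438). The proton channel gene Otop1 rose by 2.63, Esrrg by 2.73, the lipid droplet gene Plin5 by 1.99 and the thioesterase gene Acot2 by 1.65 on the log2 scale.

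Several genes named in advance did not pass. Ucp1, the uncoupling protein of brown fat, was 10.60 and 7.42 in WT and 13.79 and 10.06 in the libraries labelled knockout, so the groups overlapped (log2 fold change 2.92 ± 1.54, SE; limma adjusted p = 0.336). The Ucp1 change was 4.50 without WT replicate 1, 1.33 without WT replicate 2, 1.05 without knockout-labelled replicate 1 and 4.78 without replicate 2. Cidea, Elovl3 and Cox7a1, which mark brown and beige fat, had log2 fold changes of 3.08 ± 0.59, 4.22 ± 0.89 and 3.57 ± 0.55 with adjusted p-values of 0.0711, 0.0825 and 0.055. The deiodinase gene Dio2 (-0.08 ± 0.97) and the regulator Prdm16 (0.02 ± 0.13) lay near 0, with adjusted p-values of 0.972 and 0.957. Dio2 was 0.73 without WT replicate 1, -0.89 without WT replicate 2, -1.34 without knockout-labelled replicate 1 and 1.18 without replicate 2. Prdm16 was -0.02 without WT replicate 2. In the list of UCP1-independent thermogenesis, 1 of 14 members rose, Gpd2 of the glycerol phosphate shuttle by 2.26, and adjusted over the list alone 5 were higher and 1 lower. Its median was 0.18 (0.39 without knockout-labelled replicate 1 and 0.40 without replicate 2) and its mean -0.10 (camera adjusted p = 0.0615; adjusted p = 0.456 with an estimated correlation). Camera called it upward without WT replicate 1 (adjusted p = 0.0224), without knockout-labelled replicate 2 (0.0204), with a filter on a mean of 8 (0.0401) and without the muscle genes (0.0335).

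**Figure D1:**
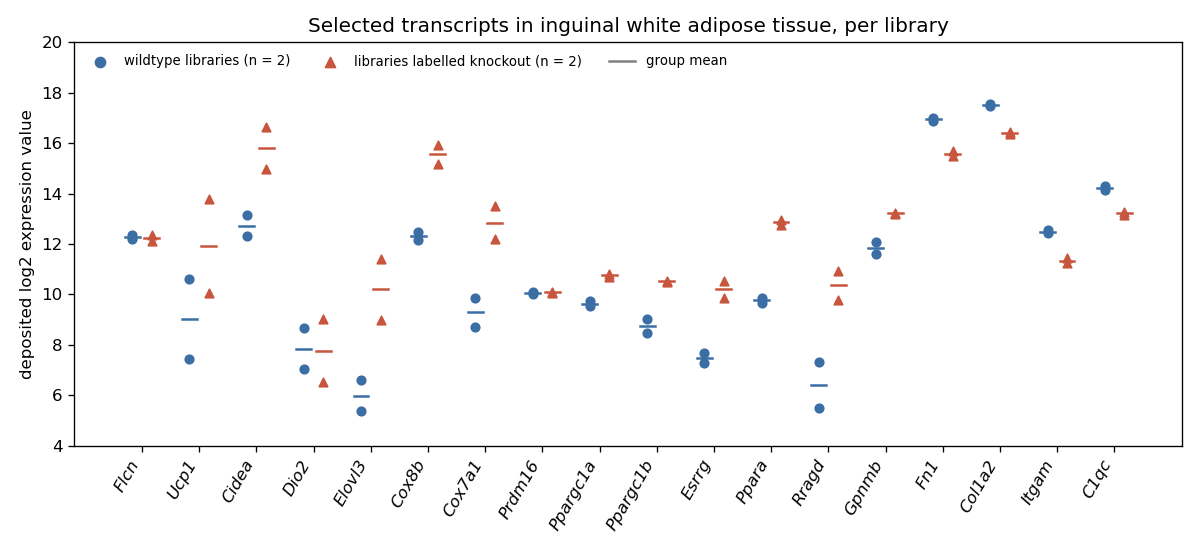
Deposited log2 expression values (vertical axis) of 18 transcripts in the WT libraries (circles) and the libraries labelled knockout (triangles), with group means as bars. Flcn overlaps between groups, Cox8b rises from 12.32 to 15.56, Ucp1 overlaps, and Fn1 falls from 16.94 to 15.59.

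Of the 37 complex I genes of mitochondrial respiration, 1 rose over all genes, Ndufv1 by 1.12 ± 0.13 on the log2 scale (SE, n = 2 per group; limma adjusted p = 0.0422), and 29 were higher and 0 lower when adjusted over the list alone. The complex I median was 0.69 (camera adjusted p = 1.01e-14; adjusted p = 0.458 with an estimated correlation). In complexes II and III, 3 of 14 genes rose (Sdhb, Uqcrc1 and Cyc1), 13 when adjusted over the list alone, with a median of 0.88 (camera adjusted p = 9.58e-10; 0.456 as adjusted p with an estimated correlation). In complex IV, 2 of 15 rose, Cox8b and Cox5b, 9 when adjusted over the list alone, with a median of 0.81 (0.49 without knockout-labelled replicate 1; camera adjusted p = 1.73e-06; adjusted p = 0.458 with an estimated correlation). Of 16 ATP synthase genes limma called 0 over all genes (12 higher at an unadjusted p under 0.05), and 10 were higher when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 4.19e-06; adjusted p = 0.456 with an estimated correlation).

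In the tricarboxylic acid cycle 3 of 22 genes rose (Ogdh, Dlat and Sdhb), 20 when adjusted over the list alone, with a median log2 fold change of 0.90 (camera adjusted p = 2.62e-13; adjusted p = 0.456 with an estimated correlation). In fatty acid oxidation 3 of 27 rose, 21 when adjusted over the list alone. These included Ppara, the nuclear receptor of fatty acid catabolism, which rose 8.57-fold (limma adjusted p = 0.0336), and the electron transfer gene Etfdh, which rose 2.98-fold (adjusted p = 0.0404). The fatty acid oxidation median was 0.97 (camera adjusted p = 6.55e-13; adjusted p = 0.456 with an estimated correlation). Of 28 genes of mitochondrial biogenesis and import 3 rose, 15 when adjusted over the list alone, and the median was 0.50 (camera adjusted p = 1.5e-08; adjusted p = 0.456 with an estimated correlation). The 3 were Esrrg, Ppargc1a and Ppargc1b, which are also counted in the thermogenic list. Esrra, a partner of the coactivators, did not pass (0.57 ± 0.14, adjusted p = 0.0991).

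The 77 mitochondrial ribosome genes had a median of 0.35, and the 78 cytosolic ribosome genes a median of -0.30 on the log2 scale. Over all genes, and also when adjusted over the list alone, limma called 0 members of either list, while 28 mitochondrial genes were higher and 25 cytosolic ones lower at an unadjusted p under 0.05. The camera adjusted p was 2.62e-12 for the first and 2.62e-07 for the second, against an adjusted p of 0.458 and 0.529 with an estimated correlation. The cytosolic library medians were 12.70 and 12.61 in WT and 12.60 and 12.17 in the libraries labelled knockout. Without knockout-labelled replicate 2 the cytosolic median was -0.11 (camera adjusted p = 0.0207, still called lower). Without replicate 1 the cytosolic median was -0.49 and the mitochondrial one 0.21. Skeletal muscle, another tissue rich in mitochondria, had marker medians of 12.67 and 9.85 in WT and 12.01 and 5.42 in the libraries labelled knockout, and so was lowest in knockout-labelled replicate 2.

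Among lists of lipid and sugar metabolism, Elovl6, which elongates fatty acids, rose 6.07-fold (limma adjusted p = 0.0444) and the acetyl-CoA carboxylase gene Acacb 2.83-fold (adjusted p = 0.0383). They were the 2 of 27 lipogenic genes that rose, and 7 were higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.54 (0.31 without WT replicate 1; camera adjusted p = 4.77e-05; adjusted p = 0.468 with an estimated correlation). The lower one, the desaturase gene Scd1, was at the ceiling of 21.66 in both WT libraries and at 20.06 in both others (limma adjusted p = 0.0536). Quantile normalization makes libraries share such top values, so its SD of 0 in each group does not measure its spread. The fatty acid synthase gene Fasn had a log2 fold change of 0.79 ± 0.31 (SE, adjusted p = 0.223), and 0.41 without WT replicate 1. In glycolysis 4 of 20 genes rose: Pfkl, Ldhb, Pgam1 and Aldoa, by 1.44, 1.49, 1.39 and 1.04. Adjusted over the list alone 11 were higher and 1 lower, and the median was 0.60 (camera adjusted p = 0.000123; adjusted p = 0.456 with an estimated correlation). In cholesterol synthesis 2 of 21 rose, Insig1 by 1.43 and Lss by 1.23, 9 when adjusted over the list alone, with a median of 0.66 (0.42 without WT replicate 1 and 0.39 without knockout-labelled replicate 1; camera adjusted p = 3.12e-06; adjusted p = 0.456 with an estimated correlation). In the list of lipolysis and lipid droplets 1 of 20 rose, Plin5, and 6 were higher and 1 lower when adjusted over the list alone (median 0.09, camera adjusted p = 0.0418; adjusted p = 0.458 with an estimated correlation). That call was lost on ranks, without the trend, without WT replicate 2 and without knockout-labelled replicate 2. The median was 0.21 without knockout-labelled replicate 1 and 0.04 without replicate 2.

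A further list held partners of folliculin and the MiT/TFE transcription factors, which control lysosomal genes, with their targets. Rragc, a Rag GTPase gene of the mTOR pathway, rose 1.94-fold (limma adjusted p = 0.0404), and Gpnmb, a lysosomal glycoprotein gene, 2.61-fold (adjusted p = 0.0463). Together with Ppargc1a and Ppargc1b these were the 4 of 15 members that rose, 8 when adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 0.000477; adjusted p = 0.456 with an estimated correlation). Rragd had the largest difference in this list, from 7.33 and 5.48 to 10.94 and 9.77, and did not pass (3.95 ± 0.72, SE; adjusted p = 0.0658). Neither did Fnip1 (0.79 ± 0.19, adjusted p = 0.103) and Fnip2 (0.56 ± 0.14, adjusted p = 0.105), which encode binding partners of folliculin. The transcription factor genes themselves were near 0 or lower without passing: Tfe3 -0.15 ± 0.12, Tfeb -0.53 ± 0.20 and Mitf 0.01 ± 0.12, with adjusted p-values of 0.531, 0.208 and 0.984. Tfe3 was -0.24 without WT replicate 1 and -0.05 without WT replicate 2, and Tfeb -0.29 without knockout-labelled replicate 1.

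Of 43 lysosomal genes 2 rose, among them the protease gene Ctsz by 1.62 on the log2 scale, and 10 were higher and 1, the protease gene Ctsh, lower when adjusted over the list alone. The lysosomal median was 0.22 (camera adjusted p = 3.5e-05; adjusted p = 0.456 with an estimated correlation). Of 18 genes of the V-ATPase, the proton pump of lysosomes, 3 rose (Atp6v1e1, Atp6v1h and Atp6v1a by 0.99, 0.89 and 0.87), 8 when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 1.39e-06; adjusted p = 0.456 with an estimated correlation). It was the 1 list that fry called (adjusted p = 0.0378). In autophagy 1 of 32 rose, Atg7 by 1.47, and 4 were higher and 1 lower when adjusted over the list alone (median 0.13, camera adjusted p = 0.025; adjusted p = 0.456 with an estimated correlation), a call lost without WT replicate 1 and without knockout-labelled replicate 2. Among 38 components of mTORC1 and AMPK signalling 1 rose, Rragc, and 5 were higher and 1 lower when adjusted over the list alone (median 0.18, camera adjusted p = 0.000962; adjusted p = 0.456 with an estimated correlation).

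**Figure D2:**
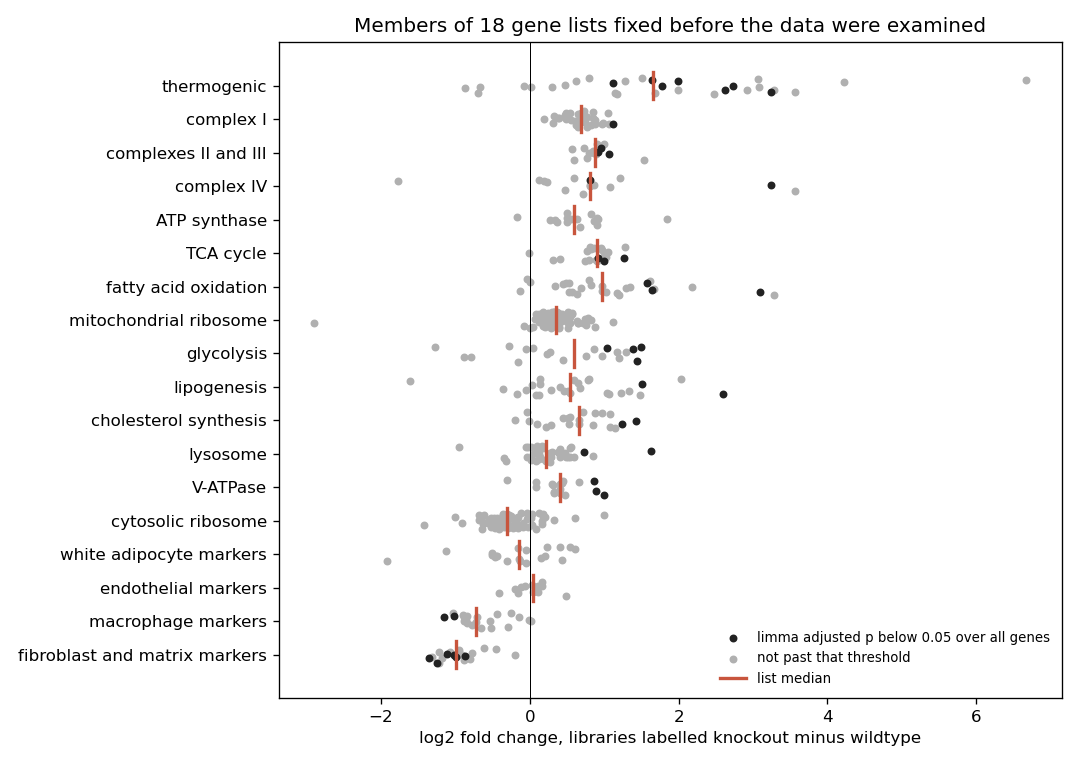
Log2 fold changes (horizontal axis, libraries labelled knockout minus WT) of the members of 18 lists, with black points past the limma threshold over all genes, grey points not past it and red bars at list medians. The thermogenic median lies at 1.66 and the complex I median at 0.69, while fibroblast and matrix markers lie around -0.99.

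Of 21 fibroblast and matrix markers 6 fell over all genes, among them Fn1, Col1a2, Col5a1 and Col6a1, and 19 were lower when adjusted over the list alone. The median log2 fold change was -0.99 (camera adjusted p = 1.01e-14; adjusted p = 0.456 with an estimated correlation). Fn1, the fibronectin gene, fell from 16.94 ± 0.10 to 15.59 ± 0.14 (SD, n = 2; 2.56-fold lower, limma adjusted p = 0.0383). Of 21 macrophage markers, the integrin gene Itgam (-1.15) and the complement gene C1qc (-1.01) fell, 12 were lower when adjusted over the list alone, and the median was -0.72 (camera adjusted p = 1.5e-08; adjusted p = 0.456 with an estimated correlation). Endothelial markers had a median of 0.05 (13 genes, camera direction down, adjusted p = 0.861; called lower without knockout-labelled replicate 2, adjusted p = 0.0386), and smooth muscle and pericyte markers 0.09 with a mean of -0.01 (8 genes, adjusted p = 0.473). Without WT replicate 2 these medians were 0.0085 and -0.10. Without knockout-labelled replicate 1 they were 0.19 and -0.05, and without replicate 2 -0.21 and -0.27. The smooth muscle and pericyte median was 0.01 without WT replicate 1. White adipocyte markers had a median of -0.14 (20 genes, adjusted p = 0.396), which was -0.08 without WT replicate 1, -0.0077 without knockout-labelled replicate 1 and -0.23 without replicate 2. Members had log2 fold changes of -0.46 ± 0.16 for Adipoq, -0.51 ± 0.66 for Lep and -0.05 ± 0.22 for Pparg (SE; adjusted p = 0.185, 0.698 and 0.925). Lep was 0.50 without knockout-labelled replicate 1, -1.52 without replicate 2 and -0.30 without WT replicate 2. Pparg was -0.33 without WT replicate 1, 0.24 without WT replicate 2, 0.07 without knockout-labelled replicate 1 and -0.17 without replicate 2.

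Of the other marker lists, most differed between single libraries. Skeletal muscle markers had a median log2 fold change of -2.48 with 0 of 19 genes called by limma over all genes, over the list alone or at an unadjusted p under 0.05. Ttn, the titin gene, shows the spread, with 13.48 and 10.93 in WT and 12.46 and 5.85 in the others. The camera adjusted p for muscle was 0.0202 (adjusted p = 0.67 with an estimated correlation), and the call was lost without WT replicate 1 and without knockout-labelled replicate 2, the latter with the opposite direction. The muscle median was -0.76 without WT replicate 1, -4.06 without WT replicate 2, -5.55 without knockout-labelled replicate 1 and 0.42 without replicate 2. Lymphocyte markers had 0 of 21 genes called (3 lower at an unadjusted p under 0.05) and library medians of 8.76 and 7.49 in WT and 8.06 and 6.51 in the others (camera adjusted p = 0.0166; adjusted p = 0.67 with an estimated correlation), lost without the same libraries. Mammary epithelium markers had a median log2 fold change of -1.31 with 1 of 6 measured genes called, Trp63 (camera adjusted p = 0.0166; adjusted p = 0.456 with an estimated correlation), lost without knockout-labelled replicate 1. Red blood cell markers had a median of -0.85 (-0.33 without knockout-labelled replicate 1) with 0 of 5 genes called (1 lower at an unadjusted p under 0.05; camera adjusted p = 0.0433; adjusted p = 0.561 with an estimated correlation), lost without WT replicate 1, without knockout-labelled replicate 1, without the trend and with a filter on a mean of 8.

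Interferon response genes had a median log2 fold change of -0.37 (20 genes, 0 called by limma, 3 lower at an unadjusted p under 0.05; camera adjusted p = 0.00441, adjusted p = 0.621 with an estimated correlation), lost without WT replicate 1 (median -0.13) and without knockout-labelled replicate 2 (-0.16). The median was -0.69 without WT replicate 2 and -0.75 without knockout-labelled replicate 1. Immediate early and heat shock genes also had a median of -0.37, with 0 of 18 called over all genes, 6 lower and 1 higher at an unadjusted p under 0.05, and 2 lower when adjusted over the list alone (camera adjusted p = 0.0468; adjusted p = 0.458 with an estimated correlation), a call lost on ranks, with a filter on a mean of 8, without WT replicate 1, without WT replicate 2 and without knockout-labelled replicate 1. Lists that camera did not call with all libraries included inflammatory cytokines (median -0.27, adjusted p = 0.31), ATF4 stress genes (-0.11, adjusted p = 0.844) and cell cycle (median -0.0018 and mean 0.05, adjusted p = 0.903). They also included neutrophil and mast cell markers (-0.83, adjusted p = 0.0719), skin markers (-0.67, adjusted p = 0.0707) and Schwann cell and nerve markers (median -0.30 and mean 0.08, adjusted p = 0.401). Adjusted over the list alone, 2 of 5 skin markers and 4 of 7 neutrophil and mast cell markers were lower. These 4 were the mast cell protease genes Tpsb2, Cpa3, Mcpt4 and Cma1. The other 3 measured markers had positive log2 fold changes, and the list mean was -0.41. The lower median of this list thus does not speak for neutrophils. The cell cycle median was 0.26 without WT replicate 1, -0.20 without WT replicate 2, -0.02 without knockout-labelled replicate 1 and 0.07 without replicate 2. Without knockout-labelled replicate 1 camera called inflammatory cytokines (adjusted p = 0.0444) and neutrophil and mast cell markers (0.00676) lower, and without WT replicate 2 neutrophil and mast cell markers (0.0362) and skin markers (0.0404). Neutrophil and mast cell markers were also called lower with a filter on a mean of 8 (0.0339). The medians without knockout-labelled replicate 2 were 0.16 for inflammatory cytokines, -0.50 for neutrophil and mast cell markers and -0.14 for Schwann cell and nerve markers. Without replicate 1 they were -0.51 for inflammatory cytokines and -0.47 for Schwann cell and nerve markers. Without WT replicate 2 they were -0.05 for ATF4 stress genes and -0.17 for Schwann cell and nerve markers. Without WT replicate 1 the ATF4 stress median was -0.17. Among the Schwann cell and nerve markers, S100b rose by 3.07 ± 0.16 on the log2 scale (SE; limma adjusted p = 0.0336), the 1 member called.

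**Figure D3:**
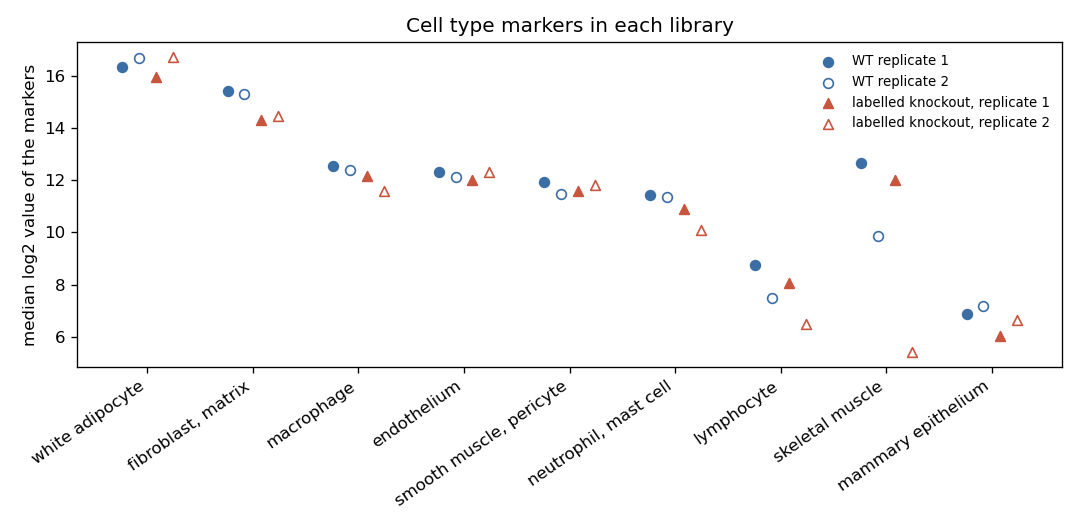
Median log2 value (vertical axis) of the markers of 9 cell types in each library, circles for WT, triangles for the knockout label, filled for replicate 1 and open for replicate 2. Fibroblast and matrix medians lie at 15.40 and 15.31 in WT and 14.31 and 14.47 in the others, while skeletal muscle medians spread from 5.42 to 12.67 without separating the groups.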

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

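The mean-8 filter, centring on abundant genes, omission of muscle genes and array weights were chosen after the data were seen; the other alternatives were set before. The filters at 0 and 2 removed 0 genes and test nothing, repeated quantile normalization and median centring barely moved the values, and voom weights on counts were not run because whole reads could not be recovered. Depth is unknown, so its limit cannot be stated. Repeated quantile normalization gave 132 higher and 84 lower genes, centring on abundant genes 134 and 83, array weights 167 and 104, and omission of muscle genes 163 and 106. Without the trend limma called 0 higher and 0 lower genes (2702 at an unadjusted p under 0.05), robust moderation called 201 higher and 143 lower, and the mean-8 filter 187 higher and 138 lower among 11311 genes, 210 of them shared with the 218. The cause was not tested, except that the filter tests fewer genes.

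Leaving out 1 library gave from 0 to 0 higher and from 0 to 0 lower genes, with 1 library alone in a group that limma assumed to vary like the other group. Of the 27 list calls, 6 were lost without WT replicate 1, 2 without WT replicate 2, 3 without knockout-labelled replicate 1 and 5 without knockout-labelled replicate 2, while 1, 2, 2 and 2 other lists were newly called. With the mean-8 filter 26 of the 27 called lists could still be tested, of which 2 were lost, and 2 other lists were newly called. With muscle genes omitted 26 could be tested, 0 were lost and 1 other list was newly called. Moderation without the trend lost 2. When 1 library was left out, the log2 fold change of Flcn ranged from -0.167 to 0.063. Changes of sign occurred for Dio2 (-1.34 to 1.18), Prdm16 (-0.0235 to 0.056), Mitf (-0.0227 to 0.034), Lep (-1.52 to 0.50), Pparg (-0.33 to 0.24), Mb (-4.23 to 0.0026), Ttn (-6.35 to 0.25), Ckm (-8.32 to 0.35), Egfl7 (-0.447 to 0.0551), Cldn5 (-0.21 to 1.19) and Hbb-bt (-0.71 to 0.14), none called in the main comparison. Camera changed direction for ATF4 stress (adjusted p 0.592 to 0.926), cell cycle (0.073 to 0.845), inflammatory cytokines (0.0444 to 0.957), skeletal muscle (6.6e-07 to 0.872), endothelium (0.0386 to 0.845) and Schwann cells (0.0571 to 0.946). With the mean-8 filter ATF4 stress (0.951) and cell cycle (0.945) also turned, and fry turned Schwann cells (0.568).

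With an estimated correlation camera called 0 of the 37 lists, and fry called 1. The adjusted p-values were 0.4563 and 0.111 for thermogenic genes, 0.458 and 0.1348 for complex I, 0.458 and 0.1221 for complex IV, 0.4563 and 0.111 for lysosome, 0.4563 and 0.111 for macrophage, and 0.4563 and 0.0745 for fibroblast and matrix markers. The estimated correlation was 0.94 for complex I and -0.029 for the V-ATPase, below the preset 0.01. Their camera adjusted p-values were nevertheless 0.458 and 0.456. The loss of calls thus does not show that the members of a list vary together. On ranks camera called 25 lists, all of them called in the main comparison. The replicate block gave 401 higher and 441 lower genes, all 218 among them. The numbers are shared between groups only as numbers, and the deviations of same-numbered libraries from their group means correlated at 0.363.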

Other observations

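The tests of explanations in this part were chosen only after the results were seen, while the gene and list tests beside them were set before the data were examined. The genes named in this and the next paragraph, and Eif3j1 below, were chosen after their values were seen. Gys2, the liver form of glycogen synthase, rose by 2.14 ± 0.15 on the log2 scale (SE, n = 2 per group; limma adjusted p = 0.0336), Gyg, which primes glycogen, by 1.88 ± 0.16, and Ppp1r3b, which targets a phosphatase to glycogen, by 2.50 ± 0.23. The phosphorylase gene Pygl and the branching enzyme gene Gbe1 had log2 fold changes of 0.98 ± 0.16 and 0.69 ± 0.17 and did not pass (adjusted p = 0.0604 and 0.10). Ucp3 rose by 2.20 and Chchd10, of the mitochondrial intermembrane space, by 2.67. mt-Nd6 rose by 2.24, but it lies opposite other mitochondrial genes and the strand setting is unknown.

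C1s1, a complement protease gene, fell by 1.17 ± 0.12 on the log2 scale (SE, n = 2 per group; limma adjusted p = 0.0374), and the complement inhibitor gene Serping1 (-1.19) fell too, while the complement genes C3 (-1.42 ± 0.32) and C4b (-0.91 ± 0.17) did not pass. Other called falls were the haptoglobin gene Hp (-1.90), the lymphatic and macrophage gene Lyve1 (-1.56), Hsd11b1, which activates glucocorticoids (-1.46), and the growth factor binding genes Igfbp6 (-1.39), Igfbp4 (-1.10) and Igfbp7 (-1.01).

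For the higher thermogenic and respiratory chain transcripts, skeletal muscle in the samples is 1 candidate source. The muscle markers argue against it: the median member difference from WT replicate 1 was -1.04 in knockout-labelled replicate 1 and -6.94 in replicate 2, while 82 respiratory chain genes had median differences of 0.97 and 0.49. Against WT replicate 2, the muscle markers of knockout-labelled replicate 1 were higher by 1.99, and those of replicate 2 lower (-3.99). Classical brown fat in the samples cannot be told apart from browning: Ucp1 changed by -0.32 relative to Cox8b, which ranged from -1.82 without knockout-labelled replicate 1 to 1.18 without replicate 2, and the brown fat genes Zic1 and Lhx8 have no values among the genes measured. A response to the knockout named by the labels also stays open.

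For the lower matrix and macrophage transcripts, a lower share of all non-fat cells would lower endothelial markers alike, but their median log2 fold change was 0.0493 with a lower quartile of -0.12, above the upper quartiles of matrix (-0.85) and macrophage markers (-0.44). The order held without each library in turn, narrowly for macrophages without knockout-labelled replicate 2, where camera called endothelium lower (adjusted p = 0.0386) and the endothelial lower quartile was -0.26 against a macrophage upper quartile of -0.30. Quantile normalization could press down genes outside the raised groups. Genes matched in mean value, 50 per marker and outside all lists, had medians of -0.0831 for matrix and -0.026 for macrophage markers, against -0.99 and -0.72. The markers were thus lower relative to other genes at their level. Because the normalization forces equal distributions, medians of so many genes lie near 0 in any case. They cannot show whether a rise shared by most genes was removed, and that possibility stays open. Among other lists of non-fat cells, medians were -0.83 for neutrophil and mast cell, -0.67 for skin and -1.31 for mammary markers. In the neutrophil and mast cell list only mast cell protease genes were lower. Red blood cell (-0.85), lymphocyte (-0.76) and skeletal muscle markers (-2.48) were lower too but depended on single libraries. Schwann cell markers lay at -0.30, smooth muscle and pericyte markers at 0.09. The endothelial markers thus speak only against a fall shared by every non-fat cell type. A lower share of several such types, fewer fibroblasts and macrophages, or lower transcript levels within them stay open as hypotheses. So does the difference in genotype that the labels name.

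Eif3j2 fell by 4.86 on the log2 scale while its near-identical copy Eif3j1 rose by 1.39, and 94.0% of the 31-base stretches of Eif3j2 occur in Eif3j1. Reads that moved between the copies would leave their sum unchanged. The sum of both changed by 0.50 ± 0.20 (SE), with log2 values of 10.41 and 10.37 in WT and 11.09 and 10.69 in the others. This is too close to its error to decide, so shared reads and a true change cannot be told apart, and a strain variant in one copy was not tested.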
